A study of Mus musculus with 11 samples.

How the data were processed

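Mammary tumours of FVB/n mice carrying MMTV-PyMT were profiled, 5 of the group called PyMT/WT and 6 of the group called PyMT/Elf5, which also carried MMTV-rtTA and an inducible Elf5 transgene. Per the labels' protocols, tumours were taken at 14 weeks of age at 7 to 13% of body weight, dissociated, and run on Drop-seq protocol 3.1 with sequencing on a NextSeq 500. Groups were taken from the sample titles. The genotype labels of the PyMT/Elf5 samples carry a number that counts up from sample to sample, and these samples were treated as 1 genotype. The labels do not say whether each sample came from a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

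The authors deposited 1 matrix of raw UMI counts per sample, with 28945 gene symbols and no normalization. Per the submitters' processing notes the genome build was mm10. The aligner and the counting tool are not given in the sources used here. The deposited barcode and gene tables hold names, not measurements. Gene identifiers and coordinates were taken from GENCODE annotation of the same build, by symbol, and 101 of the 102 named genes had a record. Ordered counts within a matrix showed a jump that parts the barcodes of PyMT/Elf5 1 and PyMT/WT 3, 4 and 5 into 2 parts, called runs here. The labels do not say what these parts are. The series design speaks of 15 tumours, and the samples hold 15 parts in all. A part may thus be a separate tumour, which would raise the number of replicates only if the parts are independent. The parts were kept together under their sample. No pair of samples had counts closer than sampling noise allows (lowest chi-square per degree of freedom 6.71 over 55 pairs). PyMT/WT 1 and PyMT/WT 3 shared 15 barcode sequences where 0.41 were expected, and the cause was not tested. Within the samples of 2 parts, barcode sequences that repeated numbered 31 in PyMT/WT 3, 5 in PyMT/Elf5 1, 1 in PyMT/WT 5 and 0 in PyMT/WT 4. Whether the parts of a sample are independent was not tested.

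Of 26613 barcodes, 20260 had at least 200 genes and at most 20% mitochondrial counts. Scrublet scores from scanpy 1.11.5 called 69 of these doublets (0.341%), too few for a working caller, and 20191 cells were used. Total counts per sample ran from 1946519 to 17042385 UMIs. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes chosen across samples, 30 principal components were computed, and cells were clustered on a shared-neighbour graph of 15 neighbours with the Leiden method at resolution 1 (igraph 0.11.9). Elf5, EGFP, PyMT and mitochondrial genes were kept out of the clustering, and milk genes were not. The epithelial marker list used for naming holds Elf5 and the milk genes Csn2, Csn3, Lalba, Wap and Wfdc18. Which cells count as epithelial is thus not independent of these genes. Clusters were named from 13 fixed marker lists, each taking the list with the highest mean log2 fold over the other cells, with a pseudocount of 10 CPM. At least 3 markers of that list had to be over 2-fold higher and detected in at least 10% of cells, and no other list could hold as many of the 10 leading genes. Clusters left, and epithelial ones, were named in a second step against the non-epithelial clusters of the first. Clusters left without a name were kept in the denominator of shares.

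Counts were summed per sample and cell class where a sample had at least 20 cells. Groups were compared per class with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood test), with Benjamini-Hochberg adjustment at 0.05, run in R 4.3.3. Log2 fold changes are PyMT/Elf5 over PyMT/WT with their standard error. Fibroblasts of PyMT/Elf5 4 (16 cells), endothelial cells of PyMT/Elf5 4 and 6 (11 and 10 cells) and T and NK cells of PyMT/Elf5 4, 5 and 6 fell below the minimum. Gene lists with at least 4 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The 28 lists covered milk, lineage, involution, matrix, endothelial, immune, stress and metabolic genes. Marker lists of the other cell classes were tested as well; those of lymphocytes, neutrophils, mast cells, Schwann cells, adipocytes, muscle and red cells had fewer than 4 tested genes in each class. Effects in epithelial cells and fibroblasts were compared with limma on samples that held both. Shares of cells were compared by exact two-sided permutation of the sample labels.

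Groups, lists, tests and thresholds were fixed before the data were examined. So was the rule for named genes. It takes Elf5, the 8 largest changes in each direction among called genes above the median level, and up to 4 members with the lowest p of each called list and of lists fixed per class. The fixed ones were milk, luminal progenitor, hormone-sensing and basal genes in epithelial cells, involution and fibrillar matrix in fibroblasts, junction and angiogenesis genes in endothelial cells, and tissue-remodelling and MHC class II genes in macrophages. Where fewer than 6 genes passed, it takes the 3 lowest p in each direction. Genes outside the rule were chosen after their values were seen. In the report these are EGFP, PyMT, Csn2, Wap, Ltf, Kit, Krt14, Krt5, Saa1, Saa3 and Mki67 in epithelial cells, Gzma and Ctla4 in T and NK cells, and Cd74 in macrophages.

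The alternatives, also fixed then, were DESeq2 1.42.0, RLE factors, no filter on low counts, cell sums over all cells, called doublets kept, a stricter cell filter (500 genes and 10% mitochondrial counts), resolution 2, at least 50 cells per sample, the replicate number as a block, log odds of shares, and leaving out each sample. The fit by edgeR was also run on counts simulated from the fitted dispersions of each class, with a common profile for all samples. It recovered 61.5% of genes changed 2-fold and 90.7% of genes changed 4-fold in epithelial cells, and 60.4 and 98.9% in fibroblasts. In endothelial cells it recovered 47.3 and 97.9%, and in T and NK cells 17.2 and 85.4%. The simulation held no runs or other structure among samples, so recovery in the real samples may be lower. Intervals of percentages are exact (Clopper-Pearson, 95%) and cover counting error only. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0.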

Results

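Single-cell RNA profiles were measured by Drop-seq, a droplet method that counts transcripts by unique molecular identifiers (UMIs), in mammary tumours of mice carrying the MMTV-PyMT transgene. MMTV-PyMT drives the polyoma middle T oncogene in the mammary epithelium. The 5 PyMT/WT samples were labelled untreated, and the 6 PyMT/Elf5 samples came from mice with a doxycycline-inducible Elf5 transgene and, per the labels, doxycycline in the food from 6 weeks of age. All tumours were harvested at 14 weeks. Doxycycline, MMTV-rtTA and the Elf5 transgene came together, so every difference between the groups belongs to all of them. Total UMI counts in the PyMT/Elf5 samples 1 to 6 were 8007827, 3892154, 7174194, 1946519, 7049517 and 4125670. In the PyMT/WT samples 1 to 5 they were 5237414, 5770577, 12844042, 10272583 and 17042385. After filtering, 20191 cells were used, with 311 to 5377 cells and a median of 803 to 3373 UMIs per cell in each sample.

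Elf5, the transcription factor that specifies milk-secreting alveolar cells, was higher in epithelial cells of every PyMT/Elf5 sample than in any PyMT/WT sample. Its level was 767 ± 315 CPM (UMI counts scaled to an equal library total; SD, n = 6) in PyMT/Elf5 and 182 ± 34.6 (SD, n = 5) in PyMT/WT. The log2 fold change was 2.19 ± 0.25 (SE, adjusted p = 2.3e-04), or 4.56-fold. Elf5 (ENSMUSG00000027186) lies on chromosome 2 from 103411688 to 103450989 in mm10. EGFP, which the gene tables also list, had a log2 fold change of 0.73 (adjusted p = 0.12), and the PyMT transcript one of −0.17 (adjusted p = 0.85), and both had counts in both groups.

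**Figure D1:**
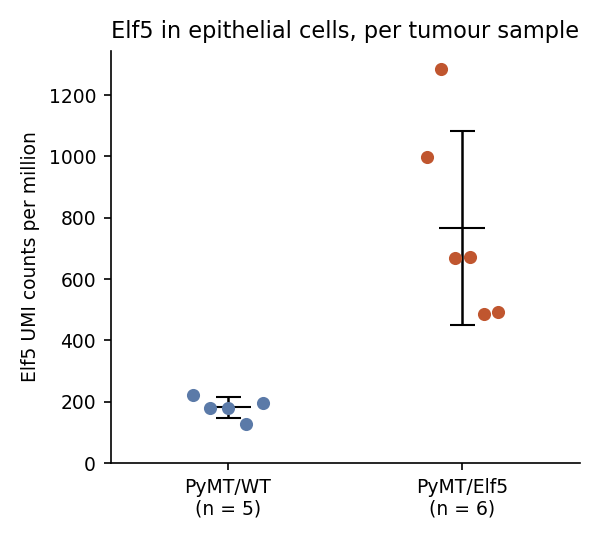
Elf5 UMI counts in CPM (y axis) in epithelial cells of PyMT/WT (n = 5) and PyMT/Elf5 (n = 6) tumours. Points are samples and bars are group means with SD, 182 ± 34.6 and 767 ± 315 CPM, and the groups do not overlap.

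The first comparison asked how the epithelial cells of the tumours differed with induced Elf5. Caseins and other secretory genes rose. Csn1s1, a major milk casein (chromosome 5, 87666208 to 87682578), rose by 3.51 ± 0.52 on the log2 scale (SE, n = 6 and 5, adjusted p = 0.0015). Its level went from 945 to 9910 CPM, higher in 6 of 6 samples. Kcne3, a potassium channel subunit (chromosome 7, 100176502 to 100184869), rose by 3.80 ± 0.23 (adjusted p = 2.6e-06), and Ly6a, the surface antigen Sca-1 (chromosome 15, 74994877 to 74998031), by 3.59 ± 0.45 (adjusted p = 8.2e-04), both in 6 of 6 samples. Cldn10, a tight-junction claudin (chromosome 14, 118787908 to 118875489), fell from 48.4 to 5.04 CPM, a log2 change of −3.18 ± 0.39 (adjusted p = 4.7e-04). Aqp5, a water channel (chromosome 15, 99590782 to 99594829), fell from 512 to 103 CPM, a change of −2.16 ± 0.23 (adjusted p = 1.6e-04). Both were lower in 6 of 6 samples than in any PyMT/WT sample. Of 12885 genes tested with edgeR, 693 rose and 713 fell. In all, 3279 genes had an unadjusted p under 0.05, where chance gives 644.

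Among the named genes with the largest changes, 5 further ones rose. Hpgd, which degrades prostaglandins, rose by 3.53 ± 0.47 (adjusted p = 0.0010). Csn1s2a rose by 3.44 ± 0.72 (adjusted p = 0.013) and the transcription factor Gata2 by 3.14 ± 0.64 (adjusted p = 0.012), all 3 in 6 of 6 samples. Csn1s2b rose by 4.05 ± 1.06 (adjusted p = 0.037) and the secreted mucin Glycam1 by 3.97 ± 1.06 (adjusted p = 0.041), each above every PyMT/WT sample in 5 of 6 samples. Another 6 fell. Among them were Car6, a secreted carbonic anhydrase (−2.95 ± 0.55, adjusted p = 0.0078), and the secretoglobin Scgb2b27 (−2.64 ± 0.60, adjusted p = 0.020). Eln, elastin (−2.53 ± 0.26, adjusted p = 1.4e-04), and the neuronal calcium sensor Ncald (−2.40 ± 0.32, adjusted p = 8.6e-04) fell as well. So did Col7a1, the collagen of anchoring fibrils (−2.28 ± 0.53, adjusted p = 0.022), and Cdkn1c, an inhibitor of cyclin-dependent kinases (−2.21 ± 0.39, adjusted p = 0.0049). Col7a1 was below every PyMT/WT sample in 5 of 6 samples and the other genes of these 6 in 6 of 6. Caseins and Scgb2b27 belong to families of similar genes, so the split of reads among members is uncertain. By cluster, 42.0% of the PyMT/Elf5 epithelial cells lay in a cluster led by Csn1s2a, Csn2 and Csn1s1 and 27.5% in one led by Spp1, Chil1 and Csn1s1. Most PyMT/WT epithelial cells lay in clusters led by 2310057J18Rik, Car6 and Scgb2b27 (30.7%), by Ltf, Chil1 and Epcam (22.4%) and by Spp1, Chil1 and Csn1s1 (19.1%). The cluster led by 2310057J18Rik held 8.67% of the PyMT/Elf5 epithelial cells, and the one led by Csn1s2a held 3.08% of those of PyMT/WT. Counts were summed over all epithelial clusters. The gene changes therefore do not tell a shift in the mix of clusters from a change within cells.

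**Figure D2:**
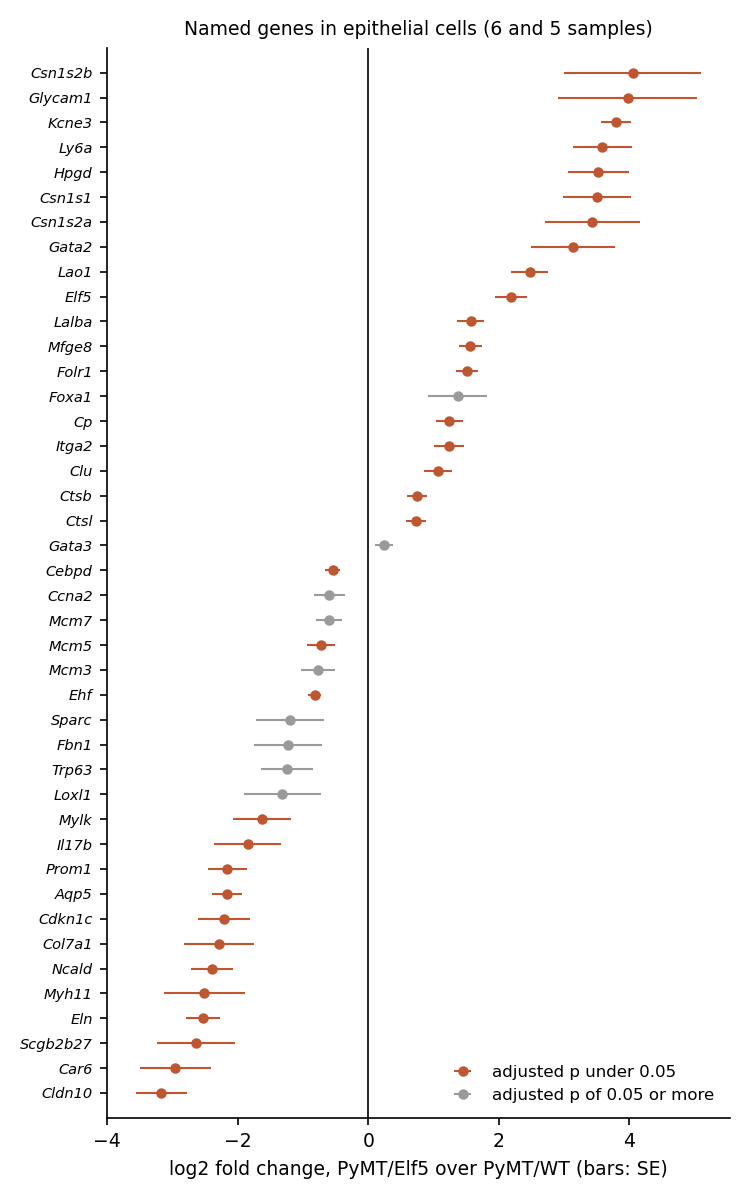
Log2 fold change (x axis, PyMT/Elf5 over PyMT/WT) of the 42 named genes in epithelial cells, n = 6 and 5. Points are estimates with SE, orange where the adjusted p was under 0.05 and grey otherwise, from Csn1s2b at 4.05 to Cldn10 at −3.18.

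The list of milk proteins and secretory alveolar genes rose in epithelial cells (camera adjusted p = 9.2e-22, and adjusted p = 0.10 with an estimated correlation). By fry its adjusted p was 0.0011. Of its 20 tested members, 14 rose and 0 fell, and 17 rose when adjusted over the list alone. Folr1, a folate receptor, rose by 1.51 ± 0.17 (adjusted p = 1.9e-04), and Mfge8, a milk fat globule protein, by 1.56 ± 0.18 (adjusted p = 2.0e-04). Lao1, an amino acid oxidase of milk, rose by 2.48 ± 0.28 (adjusted p = 2.8e-04) and Lalba, which turns on lactose synthesis, by 1.57 ± 0.21 (adjusted p = 4.5e-04). All 4 were higher in 6 of 6 samples. Of other members, chosen after their values were seen, Csn2 rose by 3.10 ± 0.60 (adjusted p = 0.0076). Wap, a whey protein, had a log2 change of 1.74 (adjusted p = 0.087) and Ltf, lactoferrin, one of 0.06 (adjusted p = 0.95).

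Of 13 luminal progenitor genes besides the induced Elf5, which is in the list, 4 rose and 3 fell, with 5 and 3 when adjusted over the list alone. Cp, the copper carrier ceruloplasmin, rose by 1.24 ± 0.20 (adjusted p = 0.0018), in 6 of 6 samples, and Itga2, a collagen-binding integrin, by 1.24 ± 0.24 (adjusted p = 0.0044), in 5 of 6. Ehf, the epithelial transcription factor next to Elf5 (chromosome 2, 103263433 to 103303278), fell from 738 to 380 CPM, a change of −0.82 ± 0.11 (adjusted p = 3.2e-04) in 6 of 6 samples, and the receptor Kit changed by −0.87 (adjusted p = 0.0074). Without Elf5 this list did not pass by camera (adjusted p = 0.651) or by fry, which tests the members alone (adjusted p = 0.305). Taking Elf5 out was chosen after the data were seen. Of 7 hormone-sensing genes, Ly6a rose and Prom1, a surface marker of these cells, fell by 2.16 on the log2 scale (SE 0.30, adjusted p = 7.6e-04, 6 of 6 samples). Foxa1 had a change of 1.37 ± 0.45 (adjusted p = 0.067). Adjusted over the list alone, 2 hormone-sensing genes rose and 1 fell. The list's camera adjusted p was 0.825, its median change was −0.10 and its mean 0.31. Genes of the basal and myoepithelial lineage fell as a list (adjusted p = 0.0027, and adjusted p = 0.918 with an estimated correlation). Of its 13 genes 0 were higher and 3 lower, and 5 were lower when adjusted over the list alone. Myh11, smooth muscle myosin (−2.51 ± 0.62, adjusted p = 0.023), was below every PyMT/WT sample in 2 of 6 samples. The cytokine Il17b (−1.85 ± 0.51, adjusted p = 0.033) was so in 6 of 6 and the kinase Mylk (−1.62 ± 0.44, adjusted p = 0.035) in 3 of 6. The keratins Krt14 and Krt5 had changes of −1.16 (adjusted p = 0.18) and −1.65 (adjusted p = 0.32). The cluster led by Krt14, Krt5 and Krt17 held 3.16% of the epithelial cells of PyMT/Elf5 and 8.21% of those of PyMT/WT.

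Each of the remaining epithelial lists that passed gave adjusted p = 0.918 with an estimated correlation. The acute phase genes of mammary involution, the regression of the gland after lactation, rose (adjusted p = 0.023), with 5 genes higher and 1 lower of 17, and 8 and 1 when adjusted over the list alone. Among them Clu, a chaperone abundant in regressing glands, rose by 1.07 ± 0.22 (adjusted p = 0.0069, 6 of 6 samples). The lysosomal proteases Ctsb and Ctsl rose by 0.75 ± 0.15 (adjusted p = 0.0073, 6 of 6) and 0.73 ± 0.15 (adjusted p = 0.0075, 4 of 6). Cebpd, a transcription factor of early involution, fell by 0.55 on the log2 scale (SE 0.12, adjusted p = 0.0089, 6 of 6). Saa1 (1.004, adjusted p = 0.025) and Saa3 (1.66, adjusted p = 0.048) rose as well, within a family of similar genes. Fibrillar matrix fell (adjusted p = 0.0020) with 1 gene lower of 19, also when adjusted over the list alone. Its named members Fbn1, Loxl1 and Sparc had changes of −1.22 (adjusted p = 0.16), −1.31 (adjusted p = 0.17) and −1.20 (adjusted p = 0.18). Markers of fibroblasts in epithelial cells, which share collagens with this list, had a median change of −0.71 (adjusted p = 0.168). Free RNA or doublets can bring fibroblast transcripts into epithelial droplets, so the fall of fibrillar matrix need not come from epithelial cells. Cell cycle genes fell (adjusted p = 0.0065) with 1 lower of 20 and 0 when adjusted over the list alone. Mcm5, of the replicative helicase, fell by 0.72 on the log2 scale (SE 0.22, adjusted p = 0.049) and lay below every PyMT/WT sample in 3 of 6 samples. The proliferation marker Mki67 had a change of −0.35 (adjusted p = 0.38). Markers of pericytes and smooth muscle cells, which a mix of cells or free RNA can bring into epithelial droplets, also fell (adjusted p = 0.023), with 2 lower of 8 and 4 lower when adjusted over the list alone. The 2 were Myh11 and Mylk of the basal list, and the 4 genes not in that list gave adjusted p = 0.559, a test chosen after the data were seen.

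Lists of other processes did not pass in epithelial cells. The involution matrix list had adjusted p = 0.617, with 3 genes higher and 0 lower of 19, and 3 and 1 when adjusted over the list alone. Mesenchymal transition had 0.825, with 2 higher of 11, also over the list alone. Its median (−0.47) and mean (−0.11) were negative where the test pointed up. Lipid synthesis had 0.704, with 3 higher and 5 lower of 19, 4 and 5 over the list alone. It had a median of −0.24 and a mean of 0.04. Hypoxia had 0.679, with 2 higher and 2 lower of 14, and glycolysis 0.598, with 2 higher and 1 lower of 13. The unfolded protein response had 0.679 (1 higher and 1 lower of 12), MHC class I 0.679 (1 higher of 8, median −0.04, mean 0.06) and interferon response 0.825 (0 of 15). Inflammatory fibroblast and complement genes had 0.918 (1 higher and 1 lower of 15, median 0.24, mean −0.08). Basement membrane had 0.825 (0 of 9), contractile genes 0.206 (1 lower of 10), luminal identity 0.238 (0 of 11) and immediate early genes 0.825 (1 higher of 14). Endothelial junction genes had 0.679 (1 lower of 7), angiogenesis 0.825 (1 higher and 1 lower of 7), MHC class II 0.825 (0 of 4), tissue-remodelling macrophage genes 0.825 (1 higher and 1 lower of 4) and mitochondrial transcripts 0.617 (0 of 6). Among markers of other cells, those of fibroblasts had 0.168 (1 lower of 17, also over the list alone), of macrophages 0.187 (1 lower of 7) and of endothelial cells 0.506 (0 of 6). Adjusted over the list alone, genes higher and lower were 3 and 2 for hypoxia, 3 and 1 for glycolysis, 2 and 1 for the unfolded protein response, 2 and 0 for MHC class I and 1 and 3 for contractile genes. They were 1 and 2 for immediate early genes, 1 and 2 for endothelial junction genes, 2 and 1 for angiogenesis, 1 and 2 for tissue-remodelling macrophage genes and 1 and 3 for macrophage markers.

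The barcodes of PyMT/Elf5 1 and PyMT/WT 3, 4 and 5 fell into 2 parts, called runs here, which the labels do not describe and which may be separate tumours. With the number of runs as a covariate, 818 genes were called in epithelial cells, 433 higher and 385 lower, and 788 of them were also called without it. Some calls were lost when 1 sample was left out. Csn1s2b in epithelial cells had adjusted p of 0.0502 to 0.0989 without any of PyMT/Elf5 1, 5 and 6 and PyMT/WT 1 to 5. Glycam1 in epithelial cells had 0.0514 to 0.0913 without any of PyMT/Elf5 1, 2, 5 and 6 and PyMT/WT 1 to 5. Mcm5 in epithelial cells had 0.0658 to 0.116 without any of PyMT/Elf5 1 to 5 and PyMT/WT 2 to 5. Mylk in epithelial cells had 0.0512 to 0.0794 without any of PyMT/Elf5 1, 3, 4, 5 and 6 and PyMT/WT 1, 4 and 5. Myh11 in epithelial cells had 0.0507, 0.0542 and 0.0559 without PyMT/Elf5 1, PyMT/Elf5 3 and PyMT/WT 4, and Il17b in epithelial cells had 0.0546, 0.0506 and 0.0594 without PyMT/Elf5 2, PyMT/WT 1 and PyMT/WT 4. Col7a1 in epithelial cells had 0.0557 and 0.0572 without PyMT/Elf5 3 and PyMT/WT 4, and Scgb2b27 in epithelial cells had 0.0534 without PyMT/WT 4.

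Other calls were gained or lost in the same way. Foxa1 in epithelial cells passed without PyMT/Elf5 1 (0.0212) or PyMT/WT 1 (0.0494). The number of genes changed in epithelial cells was 922 without PyMT/WT 4. The list markers of pericyte or smooth muscle cells in epithelial cells did not pass without PyMT/Elf5 5 (0.0551), PyMT/WT 1 (0.101) or PyMT/WT 4 (0.0582). The list involution acute phase response in epithelial cells did not pass without PyMT/WT 1 (0.0535). The number of gene lists changed in epithelial cells was 10 without PyMT/WT 2 or PyMT/WT 3, and 1, the milk list, without PyMT/WT 4 and 5 together.

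Fibroblasts were compared to ask how the tumour matrix and its fibroblasts differed with induced Elf5. In 5 samples of each group, 2 genes rose and 2 fell of 5709 tested. Csn1s1 rose by 3.82 ± 0.43 (SE, adjusted p = 0.0074), from 50.6 to 726 CPM, and Spp1, the secreted matrix protein osteopontin, by 1.07 ± 0.17 (adjusted p = 0.018), from 888 to 1790 CPM, each in 5 of 5 samples. Both also rose in epithelial cells, and free RNA or droplets with more than 1 cell can bring their transcripts into fibroblasts. Cspg4, a proteoglycan of pericytes (−1.71 ± 0.29, adjusted p = 0.026), and Egflam, a protein of the extracellular matrix (−1.89 ± 0.34, adjusted p = 0.041), fell in 5 of 5 samples. Free RNA or doublets can also bring Cspg4, a pericyte marker, into fibroblasts. Pericytes and smooth muscle cells were 1.49% of the cells in PyMT/Elf5 and 3.36% in PyMT/WT. An unadjusted p under 0.05 was found for 475 genes, where chance gives 285.

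Of the lists that passed in fibroblasts, milk had adjusted p = 0.152 with an estimated correlation and each of the others adjusted p = 0.435 with an estimated correlation. The class held 2 clusters. The one led by Clec3b, Efemp1 and Dpt made up on average 54.4% of the fibroblasts of a PyMT/Elf5 sample and 43.2% of those of a PyMT/WT sample, and the one led by Lrrc15, Col8a1 and Thbs4 made up the rest. Inflammatory fibroblast and complement genes rose (adjusted p = 0.0014, 0 of 17 genes passing singly or when adjusted over the list alone), with Cfb, a complement factor, at 1.02 (adjusted p = 0.60) and the chemokine Cxcl5 at 1.84 (adjusted p = 0.64). Fibrillar matrix rose (adjusted p = 0.025, 0 of 19, and 1 higher when adjusted over the list alone), with Col1a1 at 0.61 ± 0.17 (adjusted p = 0.33) and above every PyMT/WT sample in 5 of 5 samples, and Col3a1 at 0.44 (adjusted p = 0.55). Basement membrane fell (adjusted p = 0.025, 0 of 10, also over the list alone), with Col4a1 at −0.60 (adjusted p = 0.43). Acute phase genes rose (adjusted p = 0.033, 0 of 15, and 2 higher over the list alone), with Saa3 at 2.60 (adjusted p = 0.27) and Clu at 1.11 (adjusted p = 0.24). Involution matrix had adjusted p = 0.054 (0 of 21, and 1 higher and 1 lower over the list alone), with the protease inhibitor Timp3 at −1.19 (adjusted p = 0.27) and lower in 5 of 5 samples. Milk genes rose in fibroblasts as well (adjusted p = 4.4e-14, 1 of 11, and 5 over the list alone), as did epithelial markers (adjusted p = 0.0041, 0 of 14, and 3 over the list alone), which free RNA or doublets can give. Of these markers 5 are milk genes, and the 9 others did not pass (adjusted p = 0.9997, a test chosen after the data were seen). So did mitochondrial transcripts (adjusted p = 0.0041, 0 of 6, and 1 over the list alone). Pericyte markers fell (adjusted p = 0.020), with 1 of 4, Cspg4, passing singly and over the list alone, a fall that free RNA or doublets can give.

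Every list call in fibroblasts except milk and inflammatory fibroblast and complement was lost without some single sample. The list fibrillar matrix in fibroblasts was lost without PyMT/Elf5 1 (adjusted p = 0.114), PyMT/Elf5 2 (0.0665), PyMT/WT 3 (0.0501) or PyMT/WT 4 (0.113). The list basement membrane in fibroblasts was lost without PyMT/Elf5 5 (0.0937), PyMT/Elf5 6 (0.0783), PyMT/WT 1 (0.0553) or PyMT/WT 2 (0.197). The list involution acute phase response in fibroblasts was lost without PyMT/Elf5 3 (0.0952), PyMT/Elf5 5 (0.204) or PyMT/WT 2 (0.174), 3 (0.0772), 4 (0.0582) or 5 (0.143). The list markers of epithelial cells in fibroblasts was lost without PyMT/Elf5 2 (0.0555), PyMT/Elf5 5 (0.0982), PyMT/WT 2 (0.257) or PyMT/WT 5 (0.0509). The list mitochondrially encoded transcripts in fibroblasts was lost without PyMT/Elf5 2 (0.0674). Last, the list markers of pericyte or smooth muscle cells in fibroblasts was lost without any of PyMT/Elf5 1, 2, 3, 5 and 6 and PyMT/WT 1, 3, 4 and 5 (0.566 to 0.933).

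The gene calls rested on single samples. Csn1s1 in fibroblasts lost its call without PyMT/Elf5 2 (adjusted p = 0.0610) and after subtraction of free epithelial RNA (0.624). Spp1 in fibroblasts lost it without PyMT/Elf5 2 (0.0610), 3 (0.0589) or 6 (0.0626) or PyMT/WT 5 (0.0741). Cspg4 in fibroblasts lost it without any of PyMT/Elf5 1, 2, 5 and 6 and PyMT/WT 3, 4 and 5 (0.0587 to 0.208). Egflam in fibroblasts lost it without any of PyMT/Elf5 1, 2, 3, 5 and 6 and PyMT/WT 1, 4 and 5 (0.0596 to 0.282). After subtraction of free epithelial RNA the number of genes changed in fibroblasts was 0, so each of these calls was lost there. The number was 0 without PyMT/Elf5 2, 1 without PyMT/Elf5 6 or PyMT/WT 5, and 2 without PyMT/Elf5 1, PyMT/Elf5 3 or PyMT/WT 4. It was 7 without PyMT/WT 1 or PyMT/WT 2.

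**Figure D3:**
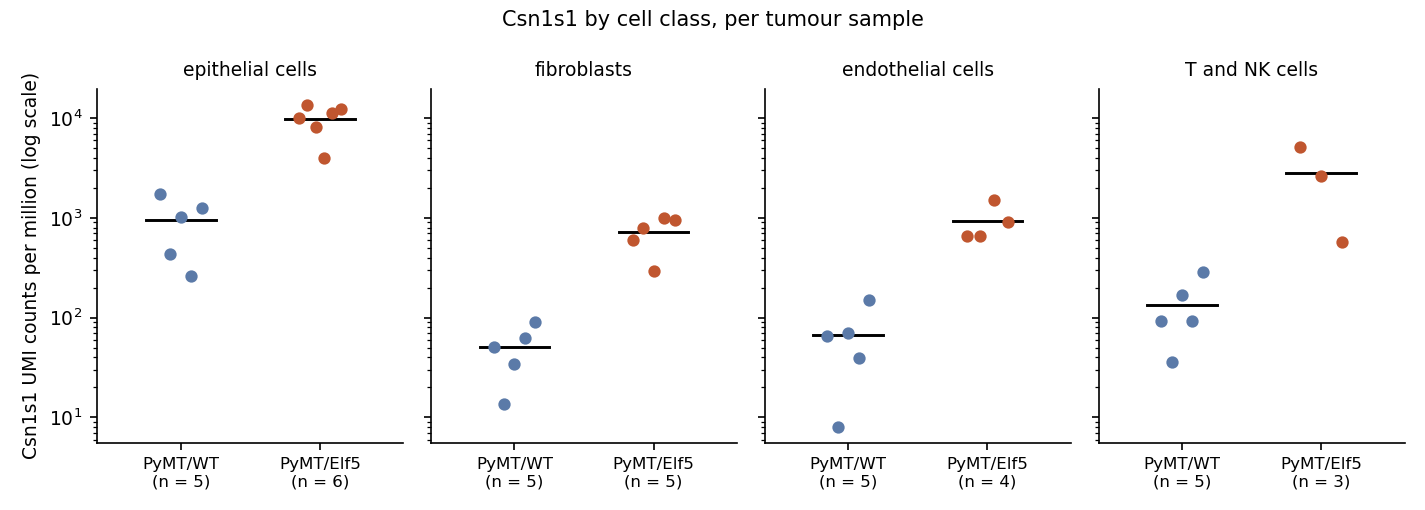
Csn1s1 UMI counts in CPM (y axis, log scale) in 4 cell classes of PyMT/WT and PyMT/Elf5 tumours. Points are samples and lines are group means, which in epithelial cells are 945 and 9910 and in fibroblasts 50.6 and 726 CPM.

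Endothelial cells were compared because the series describes leaky vessels in tumours with induced Elf5. The list of junction genes did not pass (adjusted p = 0.803, 0 of 8, also when adjusted over the list alone). Jam2, a junctional adhesion molecule, had a log2 change of 0.60 ± 0.27 (SE, n = 4 and 5, adjusted p = 0.65). The scaffold Tjp1 had one of −0.33 ± 0.22 (adjusted p = 0.77) and Esam one of −0.21 (adjusted p = 0.86). F11r stood at −0.09 (adjusted p = 0.96). With at least 50 cells per sample the sign turned for Esam in endothelial cells (0.14) and for F11r in endothelial cells (0.19). That setting kept only PyMT/Elf5 1 and 2 and PyMT/WT 1, 3, 4 and 5. Angiogenesis genes had adjusted p = 0.270 (0 of 11), with the growth factor Pdgfb at −0.55 ± 0.26 (adjusted p = 0.66). Of 3582 genes, edgeR called 0, with 265 at an unadjusted p under 0.05 where chance gives 179, and DESeq2 called 9. The genes with the lowest p were Csn1s1 (3.70 ± 0.52, adjusted p = 0.093), Csn1s2a (2.94 ± 0.49, adjusted p = 0.093) and mt-Co1 (1.203 ± 0.23, adjusted p = 0.093) above 0. Below 0 they were Irgm1, an interferon-induced GTPase (−2.02 ± 0.41, adjusted p = 0.11), Uaca (−0.90, adjusted p = 0.37) and Acsl4 (−1.05, adjusted p = 0.37).

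Basement membrane fell as a list in endothelial cells (adjusted p = 0.0022, and adjusted p = 0.475 with an estimated correlation). It had 0 of 9 genes passing singly, also when adjusted over the list alone, and Lamb1, a laminin chain, at −0.51 ± 0.21 (adjusted p = 0.63). Contractile genes rose (adjusted p = 7.1e-05, and adjusted p = 0.062 with an estimated correlation). They had 0 of 5 passing singly and 2 when adjusted over the list alone, with Cyr61, a secreted matricellular protein, at 1.41 ± 0.29 (adjusted p = 0.11). Acute phase genes rose (adjusted p = 0.0016, and adjusted p = 0.265 with an estimated correlation). They had 0 of 14 passing, and 1 over the list alone, with Clu at 2.68 ± 1.16 (adjusted p = 0.66). With at least 50 cells per sample Clu in endothelial cells was at −0.16. Glycolysis rose too (adjusted p = 0.013, and adjusted p = 0.265 with an estimated correlation). It had 0 of 10 passing, also over the list alone, with Pfkl, phosphofructokinase, at 0.66 (adjusted p = 0.64). Milk genes rose (adjusted p = 3.9e-12, and adjusted p = 0.075 with an estimated correlation), with 0 of 10 passing singly and 6 over the list alone. Epithelial markers rose (adjusted p = 5.5e-04, and adjusted p = 0.564 with an estimated correlation), with 0 of 13 and 1 over the list alone. Of these markers 5 are milk genes, and the 8 others did not pass (adjusted p = 0.154, a test chosen after the data were seen). Free RNA or doublets can give both. Mitochondrial transcripts rose (adjusted p = 2.3e-06, and adjusted p = 0.265 with an estimated correlation), with 0 of 6 and 5 over the list alone.

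Some of these list calls were lost without 1 sample. The list basement membrane in endothelial cells was lost without PyMT/Elf5 3 (adjusted p = 0.167), PyMT/Elf5 5 (0.133) or PyMT/WT 2 (0.0635). The list involution acute phase response in endothelial cells was lost without PyMT/Elf5 3 (0.106). The list glycolysis in endothelial cells was lost without PyMT/Elf5 2 (0.107), PyMT/WT 1 (0.0649) or PyMT/WT 2 (0.0615). The list markers of epithelial cells in endothelial cells was lost without PyMT/Elf5 3 (0.182) or PyMT/WT 2 (0.0635). The number of genes changed in endothelial cells was 1 without PyMT/Elf5 1, 2, 3 or 5 or PyMT/WT 3, 2 without PyMT/WT 2 and 3 without PyMT/WT 5. The number of gene lists changed in endothelial cells was 4 without PyMT/Elf5 3.

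T and NK cells were compared in 3 PyMT/Elf5 samples, with 23, 39 and 27 cells, and 5 PyMT/WT samples. Csn1s1, which T cells are not known to make and which free RNA or doublets can bring, rose by 4.28 ± 0.65 (SE, adjusted p = 0.037), from 135 to 2793 CPM, in 3 of 3 samples. It was the 1 gene called of 1192 tested. An unadjusted p under 0.05 was found for 114 genes, where chance gives 59.6. Immediate early genes fell as a list (adjusted p = 0.0064, and adjusted p = 0.510 with an estimated correlation), with 0 of 14 passing singly, also when adjusted over the list alone. Fos and Jun, transcription factors induced by stimulation and by tissue dissociation, had changes of −1.07 and −1.01. Cytotoxic genes had adjusted p = 0.388 (0 of 5), with the granzyme Gzma at 1.09, and regulatory T cell genes 0.432 (0 of 5), with the inhibitory receptor Ctla4 at 1.14. Milk genes rose (adjusted p = 8.9e-10, and adjusted p = 0.201 with an estimated correlation), with 1 of 8 passing and 5 when adjusted over the list alone. Epithelial markers (adjusted p = 7.6e-04) and mitochondrial transcripts (adjusted p = 0.0064) rose as well, with 0 of 8 and 0 of 6 passing, also over the list alone, and both with adjusted p = 0.510 with an estimated correlation. Of these markers 4 are milk genes, and the 4 others did not pass (adjusted p = 0.240, a test chosen after the data were seen). Of the named genes that did not pass, Cp stood at 2.04 ± 0.39 (adjusted p = 0.062), and mt-Nd6 at 1.67 (adjusted p = 0.075). Clint1, Hp1bp3 and Zc3hav1 stood at −1.62, −1.74 and −1.52 (each with adjusted p = 0.17).

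The call of Csn1s1 in T and NK cells was lost without PyMT/Elf5 1 (adjusted p = 0.354), PyMT/Elf5 2 (0.0599), PyMT/WT 3 (0.0924) or PyMT/WT 4 (0.0889). The number of genes changed in T and NK cells was 0 without PyMT/Elf5 1, PyMT/WT 3 or PyMT/WT 4, 5 without PyMT/Elf5 2, 2 without PyMT/Elf5 3 and 4 without PyMT/WT 5. The number of gene lists changed in T and NK cells was 1 without PyMT/Elf5 1. There, the list immediate early and dissociation response in T and NK cells and the list markers of epithelial cells in T and NK cells both had adjusted p = 0.0958. The former was also lost without PyMT/WT 3 (0.0666). Another call, the list mitochondrially encoded transcripts in T and NK cells, was lost without PyMT/Elf5 1 (0.175), PyMT/Elf5 2 (0.255) or PyMT/WT 4 (0.0541).

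Macrophages, monocytes and dendritic cells reached 20 cells in 1 PyMT/Elf5 sample, so they were compared in samples with at least 10 cells, 4 against 5, a choice made after the cell numbers were seen. MHC class II genes, which present antigen, had adjusted p = 0.522 (0 of 4, with Cd74 at 0.37), and genes of inflammatory macrophages 0.927 (0 of 9, median 0.11, mean −0.14). Milk genes rose here too (adjusted p = 1.1e-04, and adjusted p = 0.263 with an estimated correlation), with 0 of 8 passing and 3 when adjusted over the list alone. Epithelial markers (adjusted p = 0.0032) and mitochondrial transcripts (adjusted p = 0.0039) rose as well, both with adjusted p = 0.618 with an estimated correlation. Of the 7 epithelial markers 4 are milk genes, among them Csn2, and the 3 others, at 0.41 to 0.58, were too few for a test. Free RNA or doublets can give milk genes and epithelial markers. Of 828 genes, edgeR called 0, with 68 at an unadjusted p under 0.05 where chance gives 41.4, and DESeq2 called 3. Genes changed in macrophages with 10 or more cells numbered 1 without PyMT/WT 5.

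The composition of the tumours was compared as shares of captured cells. Epithelial cells were 82.1 ± 7.91% (SD, n = 6) of the cells used in PyMT/Elf5 and 49.9 ± 27.3% (SD, n = 5) in PyMT/WT (exact two-sided permutation p = 0.0173, adjusted p = 0.0505 over 7 classes). T and NK cells were 1.85 ± 1.27% against 10.5 ± 11.7% (exact p = 0.0216, adjusted p = 0.0505), and macrophages, monocytes and dendritic cells were 1.29 ± 0.685% against 3.63 ± 1.47% (exact p = 0.0130, adjusted p = 0.0505). Fibroblasts were 7.40 ± 2.23% against 10.5 ± 2.41% (exact p = 0.0563, adjusted p = 0.0788), and endothelial cells 4.47 ± 2.25% against 5.91 ± 0.842% (exact p = 0.225). Pericytes and smooth muscle cells were 1.49 ± 1.08% against 3.36 ± 2.14% (exact p = 0.104, adjusted p = 0.121) and B or plasma cells 0.0922% against 0.735% (exact p = 0.0519, adjusted p = 0.0788). None of the 7 classes passed after adjustment in this comparison, while epithelial cells and fibroblasts passed with a stricter cell filter and with named clusters as denominator (exact adjusted p = 0.0303 for share of cells by class: epithelial and for share of cells by class: fibroblast in both). Macrophages and T and NK cells passed with named clusters as denominator too. Neither setting counted cells of unnamed clusters led by epithelial genes as epithelial, and few of those cells were from PyMT/Elf5. With the stricter filter, an unnamed cluster of 460 cells, 2.83% of them from PyMT/Elf5, had 5 epithelial markers among its 10 leading genes. The named denominator left out the largest unnamed cluster of the main clustering, with 3437 cells, 1.34% of them from PyMT/Elf5. The smallest p that the 462 splits allow is 0.00433. Of the non-epithelial cells, fibroblasts were 46.7 ± 8.87% against 33.5 ± 10.4% (exact p = 0.0606, adjusted p = 0.0974) and T and NK cells 10.4% against 24.7% (exact p = 0.0260, adjusted p = 0.0974). Endothelial cells were 26.3% against 19.3% (exact p = 0.0606, adjusted p = 0.0974) and macrophages 7.67% against 10.9% (exact p = 0.108, adjusted p = 0.130). Pericytes were 8.47% against 9.59% (exact p = 0.632) and B or plasma cells 0.424% against 1.94% (exact p = 0.0649, adjusted p = 0.0974).

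The epithelial share was 77.2, 68.2, 85.0, 87.1, 85.9 and 89.0% in the PyMT/Elf5 samples 1 to 6, and 60.3, 67.7, 79.6, 22.1 and 19.8% in the PyMT/WT samples 1 to 5. Clusters with no name took 1.31% of the cells in PyMT/Elf5 and 15.4% in PyMT/WT. The largest of them, with leading genes that include the epithelial Krt18, Ehf and Car6, held 2415 cells of PyMT/WT 4 and 840 of PyMT/WT 5. This cluster got no name because the list with the highest mean fold was that of red cells, of which 0 markers met the rule. Among its 10 leading genes, 3 were epithelial markers. Counted as epithelial, a choice made after the data were seen, it brought PyMT/WT 4 to 70.9% and PyMT/WT 5 to 35.4%. The means were then 82.9 ± 7.23% and 65.0 ± 17.2% (SD), a difference of 17.9 points in place of 32.2 (exact adjusted p = 0.0707). Without PyMT/WT 4 and 5 the difference was 12.9 points (exact adjusted p = 0.167). The epithelial share of PyMT/WT 4 was 36.8% in one run and 10.7% in the other. Among samples of 1 run, 5 against 2, the mean differences in share of cells by class: epithelial, in share of cells by class: T or NK and in share of cells by class: macrophage, monocyte or dendritic were 19.1, −4.77 and −2.29 percentage points (each with exact adjusted p = 0.167). No class could have passed there, as the smallest p that so few splits allow lies above 0.05. Samples of 2 runs were 1 against 3, too few for a value. Without PyMT/Elf5 2, 6 classes passed, epithelial with a difference of 35.0 points (exact adjusted p = 0.0370), T and NK cells with −9.13 (0.0444), and macrophages with −2.48 (0.0370). Also passing were fibroblasts (share of cells by class: fibroblast) with −3.95 (0.0370), endothelial cells (share of cells by class: endothelial) with −2.21 (0.0444) and B cells (share of cells by class: B or plasma) with −0.687 (0.0463). Without PyMT/WT 3, epithelial cells (39.6), T and NK cells (−10.9) and macrophages (−2.89) passed, each with exact adjusted p = 0.0222.

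**Figure D4:**
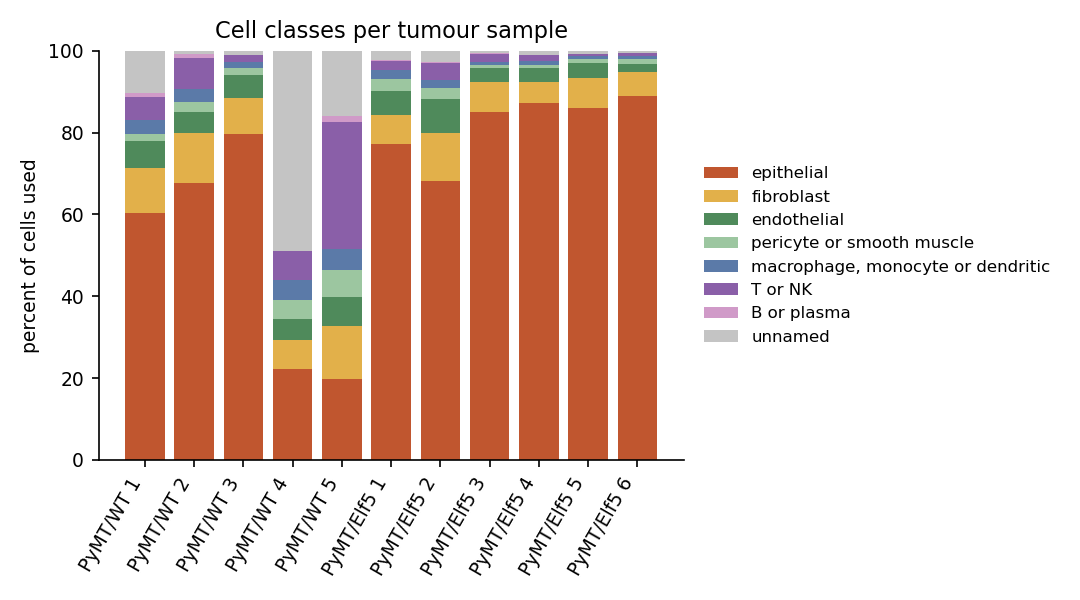
Percent of the cells used (y axis) by cell class in each of the 11 samples (x axis), as stacked bars. The epithelial part spans 68.2 to 89.0% in PyMT/Elf5 and 19.8 to 79.6% in PyMT/WT.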

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

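The test for lymph node tissue and the fit with the number of runs as a covariate were chosen after the results they concern were seen. So were the check of how haemoglobin was spread over cells and, for the unnamed cluster, the comparison of non-epithelial markers with epithelial cells.

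As a list, milk genes were higher in fibroblasts, endothelial cells and T and NK cells of PyMT/Elf5 tumours as well as in their epithelial cells, by camera at the preset correlation. With an estimated correlation the list passed in none of these classes. Of single milk genes, Csn1s1 alone passed in fibroblasts and in T and NK cells, and 0 passed in endothelial cells. Free epithelial RNA is a candidate explanation: across milk genes, classes and PyMT/Elf5 samples, the fraction of the epithelial level at which milk transcripts stood, divided by that of epithelial markers, had a median of 1.03 over 60 values, though single values ran from 0.173 to 2.17 and the median in endothelial cells was 0.767. Droplets that caught an epithelial cell with another cell were argued against as the whole cause, since 66.0% of PyMT/Elf5 fibroblasts (95% interval 61.3 to 70.4%) held a Csn1s1 UMI, against 20.2% in PyMT/WT, at a median of 3094 and 3478 UMIs per fibroblast, while 83.3% and 27.5% of epithelial cells did. A part from such droplets stays open, as the 5% of PyMT/Elf5 cells with the most held 45.2% of the Csn1s1 UMIs in fibroblasts and 69.1% in T and NK cells (53.4% in epithelial cells). Expression of milk genes by the stromal and immune cells themselves stays open, because the ratio in fibroblasts differed between the groups by −0.039 on the log2 scale (exact p = 0.921), which does not exclude a small contribution.

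T and NK cells made up 31.0% of the cells of PyMT/WT 5, far from the other 4 PyMT/WT samples. A single run of the 2 joined in this sample was argued against as the source, since the share was 28.7% in one run and 33.3% in the other, a ratio of 1.16. Lymph node tissue in the tumour piece stays open: PyMT/WT 5 held 4.85 B or plasma cells per 100 T and NK cells, below the median of 11.1 in the other PyMT/WT samples, which was the bound set for this test, but within their range of 0.288 to 17.2. A cluster led by Lef1 and Ccr7, genes of naive T cells, took 76.9% of its T and NK cells (interval 74.8 to 78.9%) against 15.3 to 65.6% in the other PyMT/WT samples. It also took 74.1% (interval 53.7 to 88.9%) in PyMT/Elf5 3 and 64.1% in PyMT/Elf5 2, which held few T and NK cells (27 and 39). In the other PyMT/Elf5 samples it took 0 to 40.0%. A high share of this cluster thus occurred without many T and NK cells and does not decide the question. No biological explanation was tested, as the design gives none within a group.

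An unnamed cluster of 3437 cells with a median of 526 UMIs took 70.3% of its cells from PyMT/WT 4, was led by epithelial genes such as Scgb2b27, Car6, Ehf and Krt18, and held epithelial markers there at 0.52 on the log2 scale over the other cells. A difference between the 2 runs of that sample is a candidate explanation for its large share there. The cluster took 75.3% of one run, with a median of 496 UMIs per cell, and 14.8% of the other, with 1692, a ratio of 5.09. It also took 15.5 and 15.7% of the 2 runs of PyMT/WT 5, so a run difference does not account for the cluster as such. Before filtering, each run of PyMT/WT 4 and 5 held 2989 to 3002 barcodes, against 431 to 2050 in each run of the other samples. What set these numbers was not tested, and it may bear on the shares of cells. Barcodes with free RNA and no cell stay open: non-epithelial markers in the cluster stood at −1.35 on the log2 scale relative to the other cells of the sample, which met the bound set beforehand against free RNA, but that bound assumed that free RNA has the mix of the captured cells, and the same markers stood 1.72 above their level in epithelial cells. Haemoglobin per epithelial marker UMI, at 0.151 times its level in named non-epithelial cells (interval 0.138 to 0.165), also met its bound set beforehand and was set aside, because 5 cells held 98.7% of the haemoglobin UMIs in those cells and 5 held 91.4% in the cluster. No biological explanation was tested.

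Among 233 groups of named-gene values, 20 had 1 sample far from the others of its group, and chance marks about 1 in 20 groups, or 11.65 of these. In CPM, the samples apart in epithelial cells were PyMT/Elf5 3 (113) and PyMT/WT 3 (4.18) for Kcne3, and PyMT/Elf5 2 (121) and PyMT/WT 4 (14.5) for Hpgd. Eln in PyMT/Elf5 2 (12.1), Cdkn1c in PyMT/WT 4 (127) and Ctsb in PyMT/WT 3 (705) stood apart too. In fibroblasts they were Col3a1 in PyMT/WT 2 (18125), Timp3 in PyMT/WT 1 (1954) and Cdkn1a in PyMT/Elf5 5 (162). In endothelial cells they were Clu in PyMT/Elf5 3 (3183) and PyMT/WT 3 (437), Lamb1 in PyMT/WT 2 (1374), Jam2 in PyMT/Elf5 5 (94.5) and PyMT/WT 1 (165), Tjp1 in PyMT/Elf5 3 (97.2) and Acsl4 in PyMT/WT 4 (323). In T and NK cells they were Csn1s2a (157) and Csn2 (394) in PyMT/WT 5 and Hp1bp3 in PyMT/WT 2 (214). Among 28 groups of shares, the fibroblast share of PyMT/Elf5 2 (11.6%) and the T and NK share of PyMT/WT 5 stood apart.

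The effect of the group differed between epithelial cells and fibroblasts for 104 of 5406 genes (limma, 5 samples of each group), 73 with the larger value in epithelial cells and 31 with the smaller. Ly6a differed by 3.01 (adjusted p = 0.0083), Hpgd by 3.36 (adjusted p = 0.0078) and Eln by −2.54 (adjusted p = 0.016), while Csn1s1 differed by 0.03 (adjusted p = 0.98).

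Other splits of the same samples were counted for each result. Chance could be excluded for the 1406 genes in epithelial cells (1 of 100 splits gave as many, the real one, highest other 52). For the 4 genes in fibroblasts, 3 of 100 splits gave as many or more, the real one included (highest other 27). For the 8 lists in fibroblasts it was 4 of 100 (highest other 8). These shares were low but not adjusted for the number of results, and other splits reached the real counts, so chance was not excluded. The split with 27 genes set PyMT/Elf5 1 and 2 and PyMT/WT 2, 4 and 5 apart and called several times the real count. What these samples share was not tested. Chance could not be excluded for the 6 lists in epithelial cells (59 of 100, highest other 19), the 7 lists in endothelial cells (24 of 100, highest other 11) or the 1 gene and 4 lists in T and NK cells (9 and 19 of 56, highest others 9 and 8). The list results concern how many lists passed in a split and do not test any single list, such as milk genes in epithelial cells. For the 0 genes in endothelial cells (highest other 9) and in macrophages (highest other 15) the count of splits decides nothing, since every split gives at least 0. In T and NK cells the split with 9 genes set PyMT/WT 3, 4 and 5 against the other samples. Those 3 hold 2 runs each, but so does PyMT/Elf5 1 among the others, so the split does not part the samples by number of runs. With the number of runs as a covariate 6 genes changed in T and NK cells.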

How the results depend on the processing

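Leaving out PyMT/WT 4 and 5, the number of runs as a covariate, leaving out the highest doublet scores, subtracting free epithelial RNA, macrophages with at least 10 cells, named clusters as denominator, the shallow unnamed cluster counted as epithelial, lists without shared genes and samples of 1 run were alternatives chosen after seeing the data. Among named genes, 2349 values kept direction and side of the threshold, 134 were weaker, 80 stronger and 10 reversed; among called lists 296 kept both and 134 were weaker. Elf5 in epithelial cells stayed past the threshold in the 9 alternatives with a recorded value (2.07 to 2.42) and without each sample (1.99 to 2.29). Its value was not recorded with the stricter cell filter, with no filter on low counts or with at least 50 cells per sample.

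The cause was not tested for the following changes unless stated. Genes changed in epithelial cells were 818 with the run covariate, 717 with the replicate block (676 shared) and 650 without PyMT/WT 4 and 5 (612 shared). Genes changed in fibroblasts were 19 by DESeq2, 97 with no filter, 12 with the stricter cell filter, 2 with the block, 2 with the run covariate, 1 with at least 50 cells and 0 after subtraction of free RNA. Genes changed in endothelial cells were 9 by DESeq2, 44 with no filter, 4 with the block, 11 with at least 50 cells, 2 without PyMT/WT 4 and 5 and 3 without the highest doublet scores. Genes changed in T and NK cells were 6 by DESeq2, 2 with RLE factors, 16 with no filter, 6 with the run covariate, 4 without PyMT/WT 4 and 5, and 0 with the block, with doublets kept or after subtraction. Genes changed in macrophages with 10 or more cells were 3 by DESeq2 and 13 with no filter.

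Gene lists changed in epithelial cells were 0 with an estimated correlation, 2 by fry and 1 without PyMT/WT 4 and 5. Gene lists changed in fibroblasts were 0 with an estimated correlation, 0 by fry, 4 with the block, 5 without PyMT/WT 4 and 5 and 4 after subtraction. Gene lists changed in endothelial cells were 0 with an estimated correlation, 0 by fry, 4 with doublets kept and 3 after subtraction. Gene lists changed in T and NK cells were 0 with an estimated correlation, 0 by fry, 2 with doublets kept and 2 after subtraction. Subtraction removes milk and epithelial transcripts by construction. Without shared genes (milk genes out of epithelial markers, basal genes out of pericyte markers, Elf5 out of its list) lists called were 5 in epithelial cells, 6 in fibroblasts, 6 in endothelial cells and 3 in T and NK cells, and pericyte markers in fibroblasts, with 1 gene left, were not tested.

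For endothelial cells, the setting of at least 50 cells kept only PyMT/Elf5 1 and 2 and PyMT/WT 1, 3, 4 and 5. There, values reversed to −0.16 for Clu in endothelial cells, 0.14 for Esam in endothelial cells, 0.19 for F11r in endothelial cells, 0.039 for Lama4 in endothelial cells and 0.034 for Lamc1 in endothelial cells. Without PyMT/WT 4 and 5, Dll4 in endothelial cells was 0.23 and F11r 0.0036, and after subtraction Mfge8 in endothelial cells was −0.47.

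With the stricter cell filter, the difference in share of cells by class: epithelial was 32.2 points and in share of cells by class: fibroblast −7.87 (exact adjusted p = 0.0303 for both). With named clusters as denominator, epithelial cells differed by 26.6, fibroblasts by −5.19 and share of cells by class: macrophage, monocyte or dendritic by −3.55 (each 0.0303), and share of cells by class: T or NK by −11.3 (0.0379). Neither setting counted cells of unnamed clusters led by epithelial genes as epithelial. The epithelial difference was 17.9 with the shallow unnamed cluster counted as epithelial and 12.9 without PyMT/WT 4 and 5. Without PyMT/WT 4 and 5, T and NK cells differed by −3.04, and share of cells by class: pericyte or smooth muscle by −0.42. The share of non-epithelial cells by class: pericyte or smooth muscle reversed to 1.08 without PyMT/WT 4 and 5 and 0.922 in samples of 1 run.

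Without each sample in turn, genes changed in epithelial cells ran from 922 to 1562 and lists from 4 to 10, in fibroblasts from 0 to 7 and 6 to 9, in endothelial cells from 0 to 3 and 4 to 9, in T and NK cells from 0 to 5 and 1 to 6, and in macrophages from 0 to 1. F11r in endothelial cells ran from −0.25 to 0.0031. Differences in share of cells by class: epithelial ran from 24.7 to 39.6, share of cells by class: fibroblast −3.95 to −2.47, share of cells by class: endothelial −2.21 to −0.936, share of cells by class: pericyte or smooth muscle −2.31 to −1.06, share of cells by class: macrophage, monocyte or dendritic −2.89 to −1.999, share of cells by class: T or NK −10.9 to −3.57 and share of cells by class: B or plasma −0.821 to −0.450. The share of non-epithelial cells by class: fibroblast ran from 9.88 to 16.2, and share of non-epithelial cells by class: pericyte or smooth muscle from −2.28 to 0.357, the latter without PyMT/WT 4.

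The stricter filter gave no value for endothelial and T and NK cells, nor did at least 50 cells for T and NK cells, and macrophages had none at 20 cells. No pairing of samples by replicate number was seen. Over 500 genes, no PyMT/Elf5 sample correlated best with the PyMT/WT sample of its number (−0.59, 0.19, −0.10, −0.67 and −0.12). With so few samples a weak pairing cannot be excluded. In T and NK cells 17.2% of simulated 2-fold changes were found, where few samples, few cells and depth were not separated.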

Other observations

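Genes in this part were chosen after their values were seen. In epithelial cells, Lpl, the lipase that takes up fat from blood, rose by 2.28 ± 0.22 on the log2 scale (SE, n = 6 and 5, adjusted p = 9.0e-05), from 21.5 to 96.5 CPM, and Fabp3, a fatty acid carrier of the lactating gland, rose by 3.10 ± 0.71 (adjusted p = 0.021). Srebf1, the regulator of lipid synthesis, fell from 355 to 175 CPM, a change of −0.90 ± 0.15 (adjusted p = 0.0018), and Fasn, fatty acid synthase, fell from 69.6 to 41.9, a change of −0.61 ± 0.16 (adjusted p = 0.030). Spp1 rose by 1.52 ± 0.23 (adjusted p = 9.9e-04), from 7234 to 19089 CPM. Snai1, a transcription factor of mesenchymal transition, rose by 1.92 ± 0.40 (adjusted p = 0.011). The matrix protease Mmp14 rose by 0.76 ± 0.18 (adjusted p = 0.016). Complement C3 rose by 1.06 ± 0.20 (adjusted p = 0.0040) and C4b fell, with a change of −1.17 ± 0.29 (adjusted p = 0.020).

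Several genes changed in epithelial cells by more than in fibroblasts of the same samples. The change in each class comes from edgeR and the difference from a limma fit to log2 CPM within samples, so the values do not subtract exactly. Srgn, a proteoglycan of secretory granules, had log2 changes of 2.48 in epithelial cells and −0.16 in fibroblasts (difference 2.83, limma adjusted p = 4.8e-04), and Ptgs1, which starts prostaglandin synthesis, 1.99 and −0.22 (difference 2.21, adjusted p = 0.0039). Colec12, a scavenger receptor, had changes of 2.80 and −0.18 (difference 2.82, adjusted p = 0.0039). Ntrk2, a neurotrophin receptor, differed by −2.64 (adjusted p = 0.019).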
